A study of Gallus gallus with 2 samples.

How the data were processed

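Single-cell RNA sequencing libraries (10x Genomics 3' chemistry) of chicken embryonic gonads at Hamburger-Hamilton stage 28 were analysed, 1 from a pool given as 7 female and 1 from a pool given as 7 male embryonic gonads, which leaves open whether 7 embryos were used. The labels gave the sex of each library. The deposited matrices held raw UMI counts per gene and barcode with no filter on barcodes, and the ratio, CPM and log2 values in the text were computed from these counts. Reads were processed with Cell Ranger 5.0.0 on the GRCg6a genome per the submitters' processing notes, whereas the file headers give Cell Ranger 4. The annotation release and the handling of intronic reads were not given in the sources used here. Each file listed 23910 genes and 6794880 barcodes. Gene symbols were those paired with Ensembl identifiers in the files, and 3507 of the tested genes had no symbol. No genome annotation of this build was used, so no coordinates are given and Z- and W-linked genes were taken from lists fixed in advance. Reads of near-identical gene copies on the Z and W chromosomes may therefore be split.

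Designs, gene lists, markers, named-gene rules and 19 alternatives were fixed before the data were examined, and 3 alternatives were added after. Barcodes were called cells above the 99th percentile UMI count of the leading barcodes divided by 10, which gave a minimum of 4801 UMIs in the female and 3838 in the male library. Of 5774 and 8007 such barcodes, none had under 500 genes, and 71 and 63 were removed for a mitochondrial share over 20%. Scrublet (in scanpy 1.11.5, expected rate 0.06) then marked 124 (2.17%) and 243 (3.06%) as doublets, which were removed. Of these, 10 and 6 carried at least 3 germ cell markers. Scrublet marked under 0.5% of cells in both libraries with the UMI minimum halved and in the female library with a mitochondrial limit of 10%, and none were removed there.

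Cells of both libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden algorithm at resolution 1.0 (igraph 0.11.9). Genes of the signalling lists and Z-linked, W-linked and mitochondrial genes were left out. A cluster was named after a class when at least 3 of its fixed markers, and more than of any other class, were over 2-fold above the other cells, with 20 CPM added to both levels. A class was compared by share only if no cluster of it had more markers of another class than of its own among its 10 leading genes.

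For the comparison of PGC-like with somatic cells, UMI counts were summed per library over PGC-like cells (123 and 100) and over cells neither PGC-like nor blood-like (5166 and 7358). The 4 sums were tested with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with library as a block and Benjamini-Hochberg adjustment at 0.05. The fit had 1 residual and 449 prior degrees of freedom. The library block pairs sums made from the same library. Nothing in the labels gives more than 1 library per sex, so p-values and SE measure only the spread between these libraries, nearly all of it shared across genes. Named genes were the 12 largest positive and 8 largest negative log2 fold changes among genes with a symbol, at least 4-fold in each library and 100 UMIs, and up to 4 members of each list. Where a side had 0 UMIs, a floor of 3 counts over both libraries was used and the fold is a bound. With 1 to 3 UMIs, the ratio of pooled counts is given with its interval. DESeq2 1.42.0 served as an alternative.

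Male and female values were compared without a test. Sums per class were scaled to CPM, with exact Poisson intervals, exact conditional intervals for ratios and exact Clopper-Pearson intervals for shares, all at 95%. Genes needed 100 UMIs over both libraries, which 7423 genes had in PGC-like and 12391 in somatic cells. The PGC-like sums held 4594332 female and 3425336 male UMIs, and the somatic sums 59529206 and 74255736. List medians were placed among 10000 random lists of the same size matched on expression. Named were the 6 highest and 6 lowest genes outside the Z- and W-linked lists and haemoglobin, the 4 highest and 4 lowest Z-linked genes and the sex determination lists. Chromosomes were taken from the fixed lists, and for 25 genes also from the RefSeq gene table of assembly GRCg7b, where 23 matched by symbol or synonym. Members of other lists were named after their values were seen. Single values of 3 list members are not reported here, and 1 of these genes is left out of the plot of Z-linked genes in addition to UBAP2, but they count in list totals and medians.

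Free RNA was estimated from barcodes with 1 to 100 UMIs, scaled by haemoglobin, and made up at most 3.34% of female and 3.72% of male somatic UMIs. With barcodes of 200 to 499 UMIs the shares were 2.46% and 1.93%. Both profiles were subtracted as alternatives.

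The test was tested on simulated counts for the comparison of PGC-like with somatic cells. Only 67, 67 and 66 genes were changed, by 1.5-, 2- and 4-fold in both directions, with a dispersion of 0.01. In the data 9605 of 14403 genes were called, so the simulation did not test scaling or error control in such a setting. With equal dispersion over 14133 genes, 38.8%, 80.6% and 93.9% of genes changed by 1.5-, 2- and 4-fold were recovered and 3 of 13933 unchanged genes were called. With dispersion varying between genes (14130 genes), 16.4%, 65.7% and 90.9% were recovered and 24 of 13930 unchanged genes were called. For male against female values, lists made with a log2 ratio of 0.58 gave 0.58 in both classes, intervals covered 95.2% of genes, and 11 and 9 of 200 unchanged lists lay outside the middle 95% of random lists. These counts held counting error only, and unchanged lists came from the same genes as the random lists. They therefore checked the calculation, and not lists whose genes vary together. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.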

Results

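Gonads of chicken embryos at Hamburger-Hamilton stage 28 were profiled by droplet single-cell RNA sequencing. The data consisted of 1 female and 1 male library, each prepared from a pool of same-sex embryonic gonads, so that differences between the sexes had no replicate check. The female library held 110773039 UMIs (unique molecular identifiers, each a captured RNA molecule) and the male library 114443562, over 23910 genes. After filtering, 5579 female and 7701 male cells were kept. Intervals given for shares, levels and ratios are 95% intervals that cover counting error only.

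The makeup of the gonad was examined to find the primordial germ cells (PGCs, the embryonic precursors of eggs and sperm) among the somatic cells. Clustering gave 26 clusters, and a single cluster carried 9 of the fixed germ cell markers, among them DAZL, DDX4, PIWIL1 and Pou5f3. These PGC-like cells made up 2.20% of the female library (123 cells, exact binomial interval 1.84 to 2.62%) and 1.30% of the male library (100 cells, 1.06 to 1.58%). PGC-like cells were RNA-rich, with a median of 38594 UMIs in the female and 39399.5 in the male library, the highest of any class, against 24849.5 and 16645 in erythroid-like, 17229.5 and 14886 in supporting-like and 9644.5 and 8133 in endothelial-like cells. With the UMI minimum for a cell doubled, the female share was 3.20%. Erythroid-like cells, led by haemoglobin genes, made up 4.91% (4.36 to 5.51%) of female and 2.84% (2.48 to 3.24%) of male cells. Endothelial-like cells were 5.38% (4.80 to 6.0%) and 4.74% (4.28 to 5.24%), neural crest or chromaffin-like cells 1.56% and 1.57%, and macrophage-like cells 0.287% and 0.312%. Most remaining cells lay in 6 gonadal epithelial-like and 6 mesenchymal-like clusters, and 6 further clusters carried no name. These were not compared by share, because in each of the 2 classes the leading genes of a cluster included more markers of another class than of its own. Only 1 female and 12 male cells were mesonephric-like and 2 and 11 were steroidogenic-like.

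**Figure D1:**
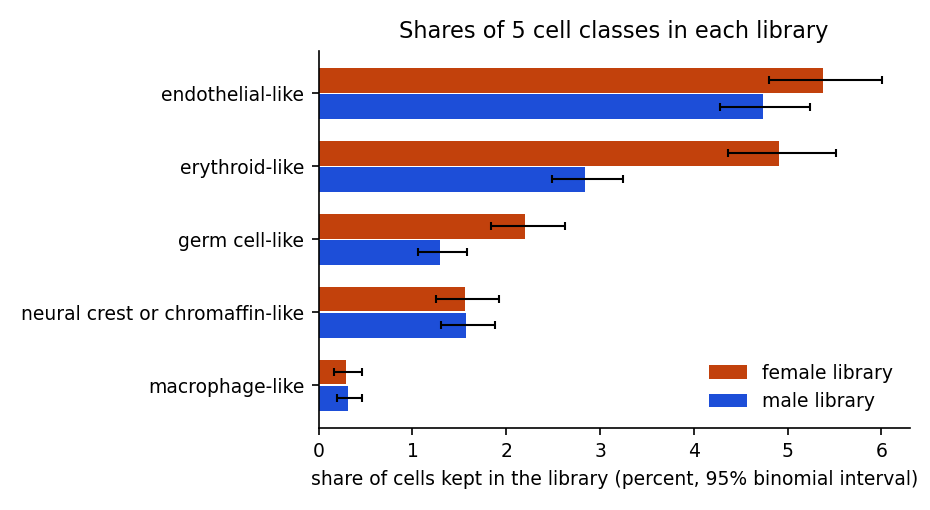
Bars show the percent of kept cells that fell in 5 named classes in the female library (5579 cells) and the male library (7701 cells), and black lines show exact 95% binomial intervals. PGC-like cells, drawn as germ cell-like, were 2.20% of female and 1.30% of male cells, and erythroid-like cells 4.91% and 2.84%.

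The title of the series asks about signalling pathways in gonadal PGCs, and PGC-like cells were therefore compared with the non-blood somatic cells of the same gonads. The largest fold changes towards PGC-like cells included those of germ line RNA-binding and piRNA genes and of transcription factor genes. DAZL (ENSGALG00000011243), an RNA-binding protein of germ cells, reached 1410 CPM (UMIs scaled to a total of 1000000 per sum of cells) in female and 1338 CPM in male PGC-like cells against 5.12 and 2.14 CPM in somatic cells, a log2 fold change of 8.36 ± 0.25 (SE, 2 libraries). Its log2 ratio was 7.73 in the female and 9.06 in the male library. SOX3 (ENSGALG00000054923; 8.68 ± 0.21) and OTX2 (ENSGALG00000034889; 8.5 ± 0.28), both transcription factors, rose more than 300-fold, with SOX3 at 8.06 in the female library alone, and so did the DM-domain gene DMRTB1 (8.37 ± 0.51) and the sodium-phosphate transporter gene SLC34A2 (ENSGALG00000014372; 8.72 ± 0.20). The piRNA pathway genes ASZ1 (8.09), MAEL (8.06) and TDRD9 (7.93), the tight junction gene CLDN1 (7.81), the vasa homologue DDX4 (7.78) and the let-7 antagonist LIN28A (7.77) completed the leading genes. FEZF2, a forebrain transcription factor gene, had 139 UMIs in PGC-like and 3 in somatic cells, a ratio of 625 (209 to 3066), and a log2 ratio of 8.08 in the female library alone.

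In the other direction, 8 genes with 0 UMIs in PGC-like cells led. HGF, the hepatocyte growth factor gene, was at least 91.6-fold lower, the homeobox gene HOXB6 at least 43.9-fold and the retinaldehyde dehydrogenase gene ALDH1A1 at least 35.9-fold, with a floor of 3 UMIs over both libraries. SMYD1, F2RL2, ZNF536, ADAMTS15 and MYCT1 were lower by at least 33.4-, 28.1-, 26.3-, 22.4- and 21.6-fold. HGF alone of these 8 also passed the threshold in DESeq2.

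Across all 14403 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 4250 were higher and 5355 lower in PGC-like cells at a threshold of 0.05. Of these, 2365 and 2537 passed 2-fold in both libraries in the same direction. Scaling by total UMIs alone moved the median log2 fold change of all genes by 0.30 and gave 5324 higher and 3905 lower, so that the higher calls were 57.7% of calls and not 44.2%. The test rested on 4 sums of counts and 1 residual degree of freedom, against 449 prior ones. The spread was therefore taken almost wholly from how far the 2 libraries departed from each other over all genes. A gene's own departure had little weight, so that its SE and p-value do not measure it. Sex differences entered the shared spread, and p-values measure only these 2 libraries. Genes that helped to form or name the PGC-like cluster are not independent evidence of the difference, whereas genes of the signalling lists were left out of clustering.

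Receptors and ligands of the KIT, chemokine and PDGF list divided between the cell types. KIT (ENSGALG00000038634), the receptor for KIT ligand, was at 208 CPM in female and 166 CPM in male PGC-like cells and at 1.39 and 0.512 CPM in somatic cells, a log2 fold change of 7.38 ± 0.19 (adjusted p = 7.33e-146 in edgeR). Its log2 ratio was 6.84 in the female and 8.12 in the male library. CXCR4, the receptor of the chemokine CXCL12, rose by 3.09 and PDGFC by 2.39. The other 7 of 10 members fell, including the ligand genes KITLG (−2.81, with −3.41 in the female and −2.22 in the male library) and CXCL12 (−3.21). PDGFRA, with 2 UMIs in PGC-like and 4036 in somatic cells, had a PGC-like to somatic ratio of 0.00668 (0.000809 to 0.0242). CXCR4, PDGFC, KITLG and CXCL12 fell outside the rule for named genes and were chosen after their values were seen, as were members named below where 5 or fewer of a list were called in a direction.

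The EGF receptor list leaned towards PGC-like cells, with 7 of 11 members higher, 3 lower and 1 not past the threshold. The receptor gene ERBB4 (4.02 ± 0.43) and the ligand genes EREG (3.55 ± 0.84) and TGFA (2.42 ± 0.70) rose. EGFR (−1.85), ERBB2 (−1.57) and EGF were lower, EGF with 1 UMI in PGC-like and 139 in somatic cells. With a floor of 3 UMIs in each library, the log2 ratio of EGF was −1.12 in the female and −0.41 in the male library. TGFA and EGF did not pass in DESeq2. In the FGF list 6 of 19 members rose and 8 fell, against 9 and 6 with scaling by total UMIs. FGF13 (3.90 ± 0.17) and the ETS factor gene ETV4 (2.07 ± 0.60) rose, ETV4 without passing in DESeq2. The decoy receptor gene FGFRL1 (−5.08 ± 0.20) and, chosen after its value was seen, FGFR1 (−1.61) fell. FGF9 had 2 UMIs in PGC-like and 995 in somatic cells.

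NOTCH genes were split evenly, with 6 of 17 higher and 6 lower. The target gene HES5 was higher by 3.44 ± 0.41, with log2 ratios of 4.70 in the female and 1.89 in the male library, a difference that was not tested. HEYL (−5.54 ± 0.34, and −4.72 in the male library alone), the ligand gene DLL1 (−2.90, and −2.18 in the female library alone) and the coactivator gene MAML2 (−2.79) fell. The receptor genes parted: NOTCH1 rose by 0.78 and NOTCH2 fell (−2.01), both chosen after their values were seen.

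The WNT, BMP and TGF-beta lists held more lower than higher genes in PGC-like cells, also with scaling by total UMIs (15 lower and 11 higher in the WNT, 9 and 4 in the BMP, and 12 and 3 in the TGF-beta list). In the WNT list 18 of 31 members fell and 9 rose. WNT6 (−5.50 ± 0.27) and WNT4 (−5.38 ± 0.24) fell, RSPO1 had 0 UMIs and was at least 10.6-fold lower without passing in DESeq2, and CTNNB1, the gene of beta-catenin, was at 81.4 and 61.3 CPM in female and male PGC-like cells against 651 and 635 CPM in somatic cells (−3.48 ± 0.18). TCF7, a WNT-pathway transcription factor gene chosen after its value was seen, rose by 3.39 ± 0.18. In the BMP list 12 of 21 members fell and 3 rose, and 1 of the calls, SMAD1 (−0.30), changed sign with scaling by total UMIs (0.00). BMP5 (−6.31 ± 0.29), BMP4 (−3.60 ± 0.21) and the BMP target ID2 (−3.27 ± 0.17) fell. The type I receptor gene BMPR1B (3.62 ± 0.26), the antagonist gene NOG (3.27 ± 0.48) and SMAD9 (0.88 ± 0.36) rose. NOG had log2 ratios of 4.66 in the female and 1.80 in the male library, and SMAD9 did not pass in DESeq2 or without the filter on low counts. In the TGF-beta, activin and nodal list 14 of 19 fell and 2 rose. INHBB (−4.23 ± 0.37), TGFB2 (−4.21 ± 0.19) and the receptor gene TGFBR2 (−3.39 ± 0.39, and −3.99 in the female library alone) fell. INHBA had 0 UMIs in PGC-like and 97 in somatic cells. A floor of 3 UMIs in each library bounds its log2 ratio only at −0.49 in the female and 0.01 in the male library. GDF3 (2.28 ± 0.25) and SKIL (0.39 ± 0.16) rose. SKIL did not pass in DESeq2, without the library term or without the filter on low counts.

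In the hedgehog list 6 of 11 members fell and 2 rose, and 3 and 1 did in DESeq2. HHIP, which encodes a hedgehog-binding inhibitor, rose by 5.80 ± 0.27 and GLI1 by 1.28 ± 0.42, GLI1 without passing in DESeq2. The coreceptor gene BOC fell (−2.95 ± 0.21). SHH and GAS1 had 0 UMIs in PGC-like cells against 64 and 106 in the much deeper somatic sums, SHH without passing when the library term was left out. With a floor of 3 UMIs in each library, the bounds on their log2 ratios were weak. These were −0.38 and −0.26 in the female and 1.15 and −0.33 in the male library. In the JAK-STAT list 4 of 10 fell, and 2 did both in DESeq2 and with scaling by total UMIs, among them SOCS1 (−2.69, and −3.69 in the male library alone) and LIFR (−2.62). IL6ST alone rose (0.59), without passing when the library term was left out. In the insulin and IGF list 11 of 21 fell and 2 rose, and 8 and 2 did when adjusted over the list alone. With scaling by total UMIs 4 rose. FOXO1 (−2.68) and IGFBP4 (−2.63) fell and IGFBP7 (0.64) rose. FOXO1 had log2 ratios of −3.79 in the female and −1.85 in the male library. Counts adjusted over the list alone were otherwise equal to those over all genes in every list.

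In the retinoic acid list 12 of 16 members tested fell and 3 rose, and 9 and 2 did in DESeq2. ALDH1A2, a retinaldehyde dehydrogenase gene, was at 22.4 and 9.05 CPM in female and male PGC-like cells against 403 and 343 CPM in somatic cells (−4.89 ± 0.19). ALDH1A3 (−4.68 ± 0.21) and the retinol-uptake receptor gene STRA6 (−5.49 ± 0.27) fell as well. The members that rose were CYP26C1 (2.75 ± 0.52) and CYP26B1 (1.74 ± 0.54), which encode enzymes that break down retinoic acid, and CRABP-I (1.02 ± 0.14). CYP26B1 did not pass in DESeq2.

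**Figure D2:**
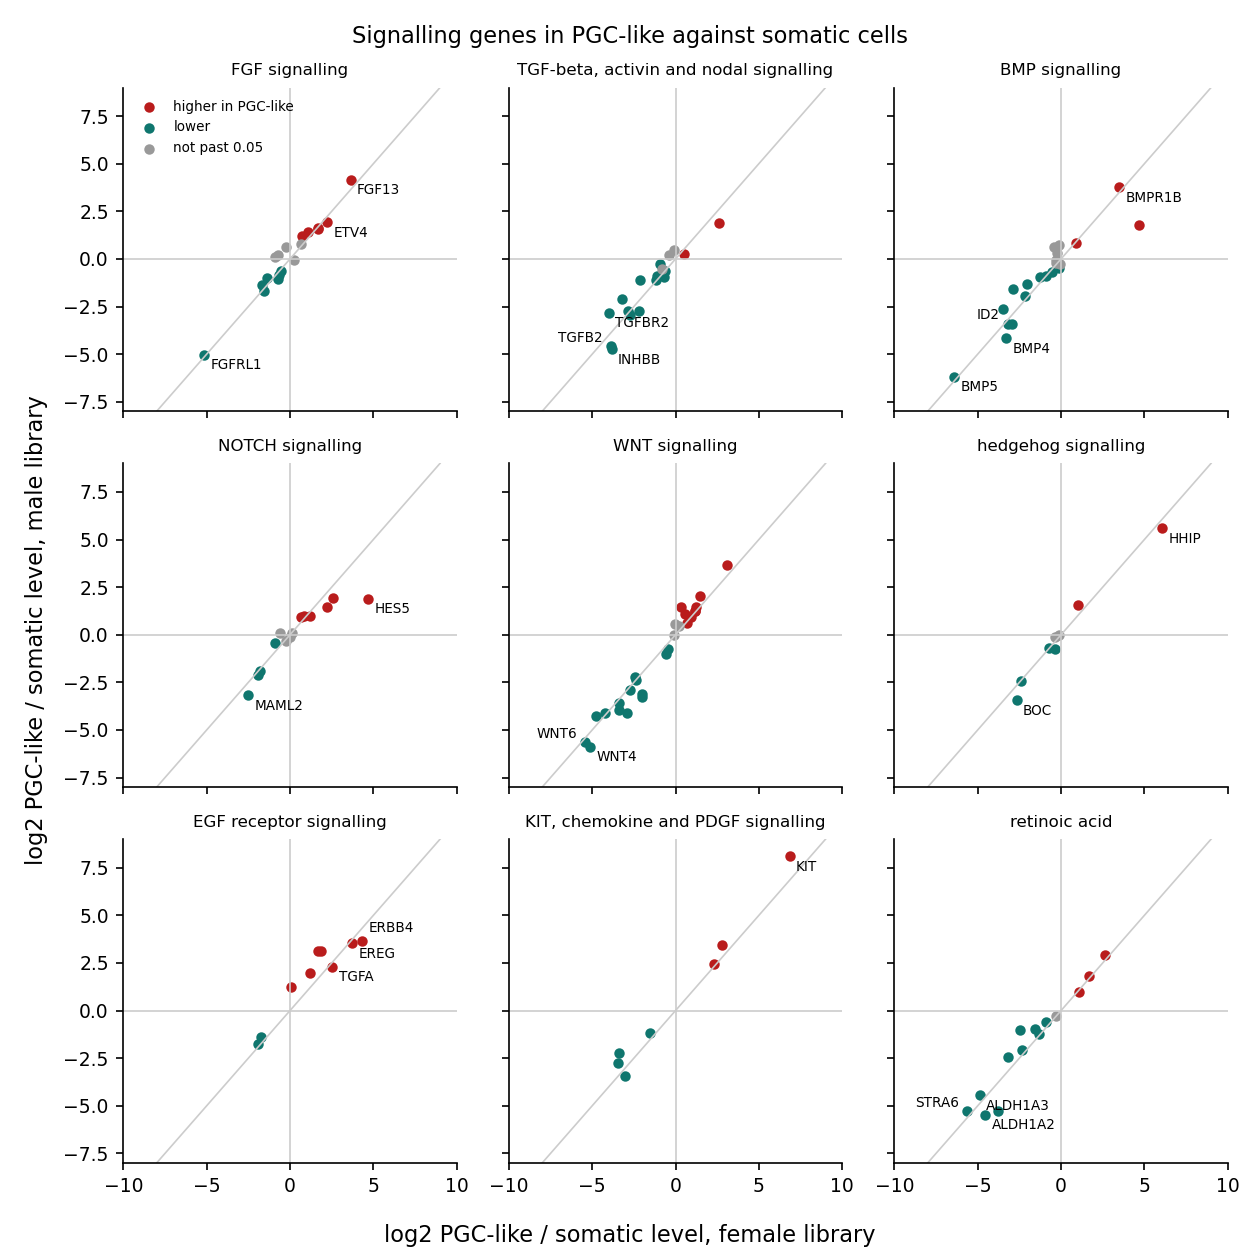
Each point is a gene of 1 of 9 signalling lists, with its log2 ratio of PGC-like to somatic level in the female library on the horizontal axis and in the male library on the vertical axis. Genes with under 3 UMIs on a side in a library are left out, the diagonal marks equal ratios, and colours give the edgeR call. With fitted log2 fold changes over both libraries, KIT (7.38) and HHIP (5.80) lie at the upper right, and BMP5 (−6.31), WNT6 (−5.50) and STRA6 (−5.49) at the lower left.

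Lists of germ line genes served as a reference for these sizes. All 12 pluripotency and early germ line genes tested were higher, led by PRDM14 (21 UMIs against 0, at least 94.4-fold), SOX3, LIN28A and NANOG (7.03 ± 0.44). All 16 piRNA and germ granule genes were higher, among them ASZ1, MAEL and DDX4. Several of these genes were also naming markers. Meiosis genes did not move together. SMC1B (6.15 ± 0.43, and 5.28 in the male library alone), HORMAD2 (3.64 ± 0.56) and HORMAD1 (3.42 ± 0.29) were higher, MSH4 (−1.27) and STAG3 (−0.95) lower, and 1 gene was not past the threshold. RAD21L1 was lower with 1 UMI against 169, without passing in DESeq2. With a floor of 3 UMIs in each library its log2 ratio was −1.45 in the female and −0.65 in the male library. Among DNA methylation genes the methyltransferase gene DNMT3B (2.72 ± 0.14) and MBD3 (0.77 ± 0.14) rose, UHRF1 rose by 0.37 with log2 ratios of 0.75 in the female and −0.010 in the male library, and the demethylase gene TET2 fell (−1.0 ± 0.22). The UHRF1 call was lost in DESeq2 and in 5 other alternatives.

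In the mitosis list 7 of 13 members fell and 0 rose, led by TOP2A (−1.72 ± 0.17) and CENPF (−1.11 ± 0.16), but 4 fell and 4 rose both with scaling by total UMIs and against gonadal classes only. In the DNA replication list 4 of 14 rose and 4 fell, against 6 and 1 with scaling by total UMIs, and 2 fell in DESeq2. CDT1 (1.38 ± 0.34, and 0.61 in the male library alone) and CCNE2 (0.88 ± 0.17) rose and MCM2 fell (−0.91 ± 0.14). Among glycolysis genes LDHA rose by 3.20 ± 0.15 and GPI (0.86) and PGAM1 (0.70) rose, whereas 7 of 13, including ALDOC (−1.49) and HK2 (−1.23), fell, and 5 rose with scaling by total UMIs. Early response and heat shock genes were lower in 8 of 11 cases, among them EGR1 (−4.68 ± 0.27), ATF3 (−4.67 ± 0.21), FOS (−3.92 ± 0.17) and JUN (−3.46 ± 0.18), while HSP90AA1 (1.55) and HSPA2 (1.34) were higher. Steroid synthesis genes fell in 8 of 11 cases, among them NR5A1 (−4.60 ± 0.22, and −5.25 in the male library alone), and FDX1 rose (1.17). All 5 male and all 6 female sex determination genes tested were lower in PGC-like cells, for example AMH (−4.82 ± 0.36), SOX8 (−3.56) and ESR1 (1 UMI against 2608). DMRT1 (−0.88 ± 0.14) lost its call with the somatic side limited to gonadal classes, and without the library term.

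The sex labels were examined through the W chromosome, which only female birds carry. HINTW (ENSGALG00000035998) had 430671 UMIs in the female and 23 in the male library, HNRNPKL 11792 and 28, and SPIN1W 3451 and 0, the last under a limit of 3 counts, 0.0262 CPM. At least 1 HINTW UMI was found in 5574 of 5579 female cells (99.9%) and in 2 of 7701 male cells (0.0260%, 0.00315 to 0.0938%). All 5 female cells without HINTW were erythroid-like, and 22 of the 23 male-library UMIs lay in 1 erythroid-like cell.

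Male birds carry a pair of Z chromosomes and females a single Z, and Z-linked genes were therefore compared between the libraries. In PGC-like cells the median log2 ratio of male to female level over 33 Z-linked genes with at least 100 UMIs was 0.78 (0.68 to 0.90), or 1.72-fold, and 32 of 33 genes were higher in the male library. In somatic cells the median over 49 genes was 0.62 (0.52 to 0.77), or 1.54-fold, with 47 of 49 higher. Both medians lay at percentile 100 of 10000 random lists matched on expression. Ribosomal protein genes led in PGC-like cells, RPL17 at 1.42, RPS23 at 1.20 and RPS6 at 1.19, together with SMAD2Z at 1.34. RAI14, LMNB1 (0.27), DMRT1 (0.34) and LIFR (0.36) were lowest, and LIFR was at −0.10 with cells thinned to equal depth. In somatic cells ISL1 (1.18), PRLR (1.10), FEM1C (0.92) and DMRT1 (0.92) were highest and VLDLR (−0.54), FST (0.03) and SYK (0.07) among the lowest. UBAP2, with 713 UMIs in female and 0 in male somatic cells, followed the W-linked genes and not the Z-linked list it was put in, and the RefSeq gene table (assembly GRCg7b) gives UBAP2 as a name of a gene on each sex chromosome. Cells were also thinned to equal depth between the libraries, at 16038 UMIs per PGC-like and 7462 per somatic cell. The PGC-like median was then 0.95 (0.48 to 1.09) over 21 genes and the somatic median 0.61 (0.45 to 0.75) over 48 genes. Depth still differed between the classes. The medians of the 2 classes also rest on different sets of genes, with and without thinning, so their difference is not one between classes alone.

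**Figure D3:**
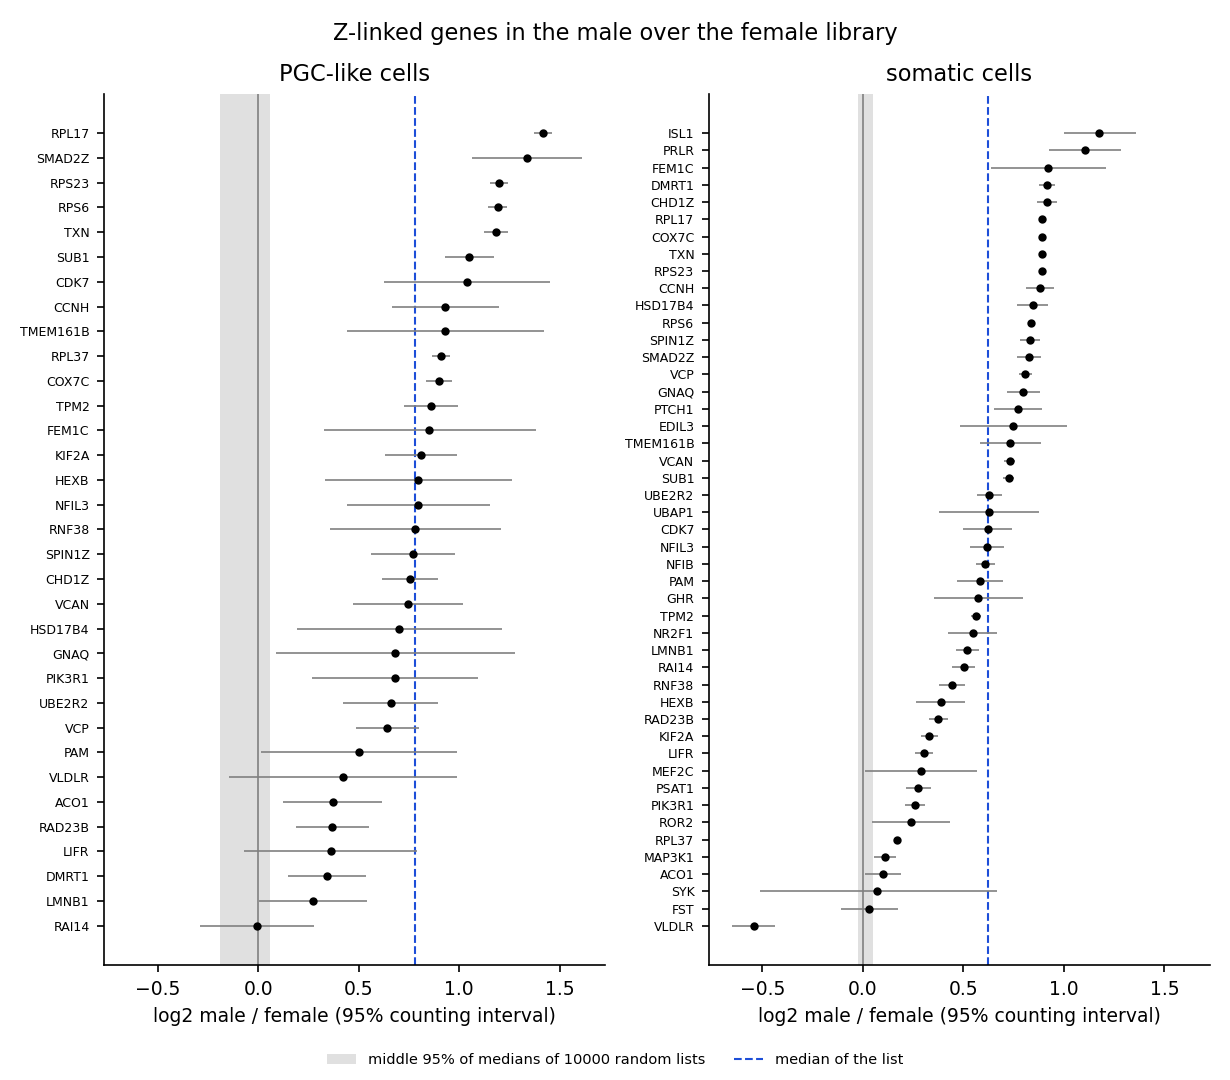
Points are Z-linked genes with at least 100 UMIs, each with its log2 ratio of male to female level and 95% counting interval, in PGC-like cells on the left and somatic cells on the right, without UBAP2. Dashed lines mark the list medians of 0.78 and 0.62, and grey bands the middle 95% of the medians of 10000 random lists of the same size.

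Male and female PGC-like cells were then set side by side, with no test because each sex had 1 library. Genes were ranked outside the Z- and W-linked lists and haemoglobin. The meiosis gene SMC1B was at 31.8 CPM (26.8 to 37.4) in female and 6.13 CPM (3.80 to 9.37) in male PGC-like cells, a log2 ratio of male to female of −2.37. SIX3, a homeobox gene, was at −2.99, IL1RAPL2 at −2.11, ZMYND11 at −1.58 and UROS at −1.53. SMAD7B had 132 UMIs in the female and 0 in the male library, at least 32.8-fold lower in male cells, which was the pattern of the W-linked genes, and the RefSeq table puts it with these. Highest in the male library were ENC1 (2.06), ADMP (1.77), the nodal coreceptor gene CFC1 (1.76), CCDC125 (1.75), the neurotensin gene NTS (1.55) and RFX3 (1.55). CFC1 was at 24.6 CPM (20.3 to 29.6) in female and 83.2 CPM (73.8 to 93.4) in male PGC-like cells. The fixed list did not hold every Z-linked gene. CCDC125 had no match in the RefSeq table, so its chromosome was not known here. That table puts ENC1, CFC1 and RFX3 with the Z-linked genes. Their ratios were nonetheless above the median of 0.78 of the Z-linked list. The intervals of ENC1 (1.44 to 2.71) and CFC1 (1.44 to 2.09) overlapped that of RPL17, the highest gene of that list (1.42, 1.37 to 1.46). ENC1, CFC1 and RFX3 were picked for high ratios among all genes ranked, which the intervals do not take into account.

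Whole lists also stood apart from random lists in PGC-like cells. Random lists were drawn gene by gene, whereas genes of a list such as mitosis can vary together. Here and below, a percentile or a count of members in 1 direction is therefore not a test of the list. All 13 mitosis genes were lower in the male library, with a median log2 ratio of −0.43 at percentile 0.00, among them CENPF (−0.82), KIF20A (−0.70) and CENPE (−0.58). With TMM scaling the median was −0.32 and 11 of 13 were lower, and with cells thinned to equal depth it was −0.28 over 12 genes. The piRNA and germ granule list had a median of −0.38 (percentile 0.10), with 10 of 12 members lower, including TDRD15 (−1.29) and TDRD12 (−0.78), but DDX4, which the RefSeq table puts with the Z-linked genes, was higher (0.62). The 3 meiosis genes with enough UMIs, SMC1B, STAG3 (−0.97) and HORMAD1 (−0.89), were all lower, and with cells thinned to equal depth STAG3 was at −0.34 and HORMAD1 at −0.35. The pluripotency and early germ line list had a median of 0.29 (percentile 99.5), with 6 of 7 members higher, including Pou5f3 (0.66) and SOX3 (0.57). With cells thinned to equal depth the median was 0.12 over 5 genes, with LIN28B at −0.14. Haemoglobin, RNA of blood cells, was also lower in male PGC-like cells, with a median of −1.02, and made up 0.184% of female and 0.0930% of male UMIs there. JAK-STAT genes had a median of 0.36 (5 genes, percentile 99.4), which was the value of the Z-linked LIFR.

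**Figure D4:**
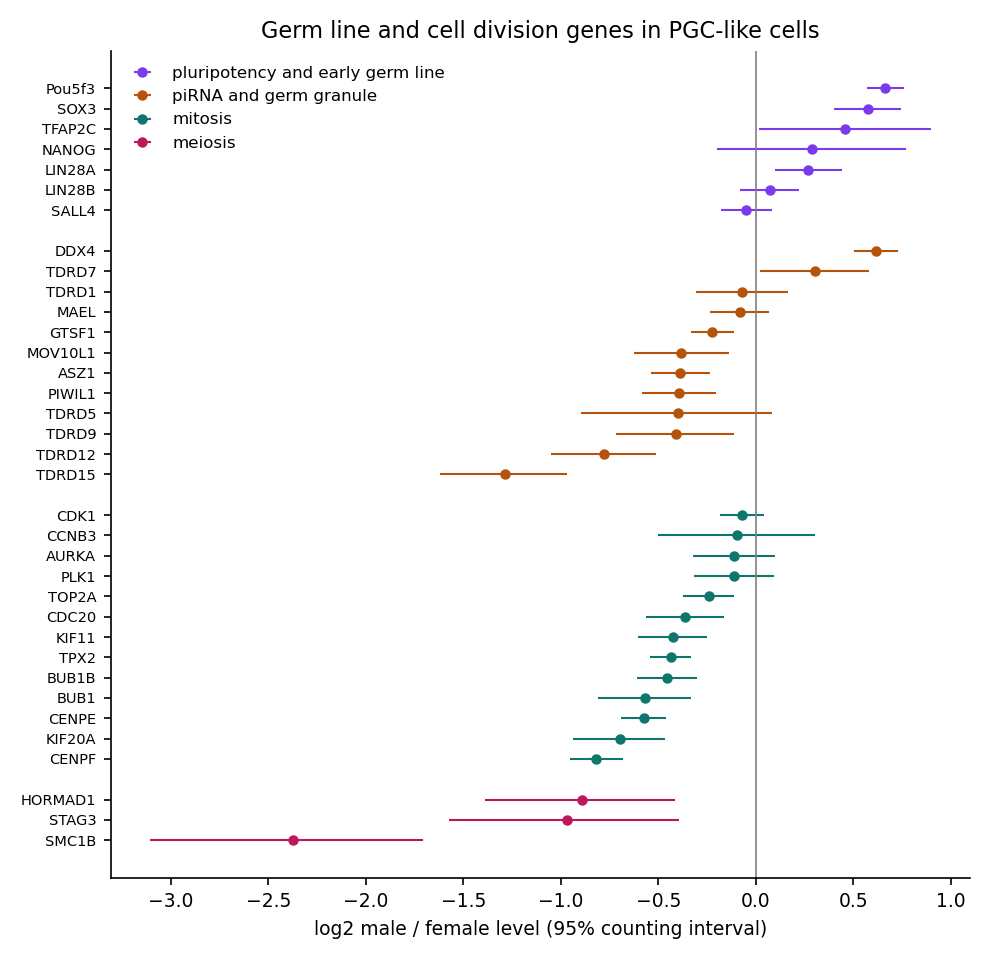
Points show the log2 ratio of male to female level in PGC-like cells for each gene with at least 100 UMIs of 4 lists, with 95% counting intervals. The 13 mitosis genes and the 3 meiosis genes lie below 0, and 6 of 7 pluripotency and early germ line genes above it.

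In somatic cells the sex determination genes were compared. The male list had a median log2 ratio of 0.75 (percentile 100). AMH, the anti-Müllerian hormone gene, was at 14.5 CPM (13.6 to 15.5) in female and 27.9 CPM (26.7 to 29.1) in male somatic cells, a log2 ratio of 0.94, and SOX9 was at 0.75, SOX8 at 0.07 and PTGDS at −0.22. Somatic clusters were also weighted equally, over the 20 with at least 500000 UMIs in each library. This left out the mesonephric-like and steroidogenic-like clusters. The list median was then 0.23, with AMH at 0.45 and SOX9 at 0.23. DMRT1 (0.81) was higher in the male library in 19 of the 20 clusters, AMH in 13 and SOX9 in 14. A cluster led by CYP17A1 and AMH, named supporting-like, held 100 female and 395 male cells. Equal weights take out this difference in size, and so part of the AMH ratio. Its share was not compared because sex-biased genes defined it. In the female list, with a median of −0.02, WNT4 was at −0.03, RSPO1 at −0.19, ESR1 at −0.02 and CTNNB1 at −0.04. FOXL2, an ovarian transcription factor gene, had only 16 female and 11 male UMIs, and the aromatase gene CYP19A1 had 1 and 8, so that a difference was not detectable at this depth in somatic cells as a whole. In supporting-like cells alone FOXL2 had 5 female and 3 male UMIs (a log2 ratio of −2.52, −5.21 to −0.16), FST was at −1.91 (−2.79 to −1.03) and WNT4 at −0.48 (−0.65 to −0.30), with counting intervals only, whereas CTNNB1 was at 0.12 and ESR1 at 0.07. The list median over the 3 genes with at least 100 UMIs there was 0.07.

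Steroid synthesis genes were higher in male somatic cells, with a median of 0.28 (percentile 99.97) and 8 of 9 members higher, HSD3B1 at 0.91, the Z-linked HSD17B4 at 0.84 and CYP17A1 at 0.61, whereas HSD17B1 was lower (−0.84). With clusters weighted equally the median was 0.11, CYP17A1 was at −0.13 and HSD3B1 at 0.32. These values do not hold the steroidogenic-like cluster (2 female and 11 male cells). Retinoic acid genes were lower in male somatic cells in 12 of 14 cases, with a median of −0.22 (percentile 0.00), or −0.14 with clusters weighted equally. These included the retinol dehydrogenase gene RDH10 (−0.54) and DHRS3 (−0.39), whereas CRABP-I was higher (0.61). Replication and mitosis genes were slightly higher, with medians of 0.14 and 0.11 at percentiles 99.95 and 99.94, but with clusters weighted equally these were 0.10 and 0.01. Some clusters were themselves led by replication or mitosis genes such as RRM2, CDC20 and CENPF. Equal weights take out differences in the size of such clusters, so these values cannot show whether the share of dividing cells differed. Early response and heat shock genes were slightly lower at −0.14 (percentile 0.00).

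Outside the Z- and W-linked lists and haemoglobin, the single genes with the highest male to female ratios in somatic cells were carried by few cells. CYP2AC1 (2.76), PDZK1 (2.71) and SULT1C3 (2.65) had 97.2%, 90.6% and 90.1% of their male UMIs in the 12 mesonephric-like cells. Equal weights left these cells out. Over the 20 clusters used the genes were at 0.53, −1.11 and 0.15, on few remaining UMIs. PDZK1 had no match in the RefSeq table. CYP2AC1 was at 4.60 with a mitochondrial limit of 10%. CPA6 (2.69), EN2 (2.57) and RLN3 (2.52), a relaxin family gene that the RefSeq table puts with the Z-linked genes, were found in 102, 67 and 68 of 7358 male cells, with 71 of the 271 male RLN3 UMIs in a single cell. Highest in the female library were SMAD7B (1047 UMIs against 3, a log2 ratio of −8.77 with an interval of −11.05 to −7.21) and 5 genes of secreted defence proteins, LECT2 (−3.41), CATHL2 (−3.28), DEFB4A (−3.19), AvBD1 (−2.90) and BD7 (−2.68). These 5 genes reached only 3.29 to 5.19 CPM in female somatic cells. With free RNA subtracted by the profile of barcodes with up to 100 UMIs BD7 was at −1.82, whereas the other 4 lay further below 0 than without it and within counting error. Subtraction by the profile of barcodes with 200 UMIs or more but under 500 left under 3 UMIs of these genes in at least 1 library, so that no ratios are given for it. Haemoglobin made up 0.461% of UMIs in female and 0.283% in male somatic cells.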

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

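The tests of free RNA and of a few cells for the antimicrobial genes, and of scaling for the mitosis genes, were chosen after the result was seen. How both Z-linked tests were read, with draws of cells added, and the use of the list interval for the mitosis genes, were revised after their values were seen.

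UHRF1, a DNA methylation factor gene, was higher in PGC-like cells of the female library only, with a log2 ratio of PGC-like to somatic level of 0.75 in the female and −0.010 in the male library, and this difference was not tested. Barcodes with 200 UMIs or more but under 500, which no comparison used, held signals of several cell types. Haemoglobin made up 18.7% of their UMIs in the female and 14.7% in the male library. Antimicrobial peptide genes summed to 902 and 164 CPM there, and germ cell markers to 273 and 220 CPM.

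Antimicrobial and defence genes (LECT2, CATHL2, DEFB4A, AvBD1 and BD7, leaving out SMAD7B) had a median log2 ratio of male to female level of −3.19 in somatic cells. A few producing cells were argued against, because the 10 female somatic cells with most of these UMIs held only 2.47% of them, and a UMI was found in 1151 of 5166 female and 203 of 7358 male somatic cells. Free RNA may account for the level, since the median of somatic over free-RNA level was 1.08 in the female and 0.938 in the male library with the profile of the barcodes with 200 UMIs or more but under 500, but it was 2.52 and 2.03 with that of 1 to 100 UMI barcodes. The profile keeps this open. Sex cannot be told apart from other differences between the libraries, with 1 library per sex.

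HINTW was found in 1 erythroid-like cell of the male library with 22 UMIs, and was missing in 5 erythroid-like cells of the female library. Barcode exchange was argued against by 0 UMIs of the male cell's barcode in the female library, and low depth by only 0.0014 female cells expected to lack HINTW. The 5 female-library cells had 1.18 times the Z-linked share of the others (interval 1.05 to 1.32). This met both bounds named in advance, above 1 for cells of the other sex and below the male to female ratio of 1.49 against them, and so decided nothing. The draws added later argued against cells of the other sex as the source of all 5. Their share of 2.04% lay below the middle 95% of 10000 draws of 5 male-library cells (2.12 to 2.99%). With draws from the 40 cells nearest in depth, however, that range began at 2.02%. Among draws of 5 female-library cells with HINTW (middle 95% of 1.42 to 2.10%), 96.0% lay at or below it. What made these 5 cells differ stays open. A cell of the other sex may account for the male-library cell, which had 0.689 times the share of the others (0.581 to 0.811) against 0.670 between libraries, but its 1.78% of Z-linked UMIs lay within the 5th to 95th percentile range of male cells, 1.68 to 3.30%.

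Mitosis genes were lower in male than in female PGC-like cells, with a median log2 ratio of −0.43 over 13 genes. Free RNA was argued against by a median of −0.43 (interval −0.58 to −0.12) with background subtracted, and a few cells by a median of −0.38 (−0.55 to −0.23) without the 10% of cells with most mitosis UMIs. Scaling was argued against as well, because a factor shared by all genes moves random lists as much, and the list lay at −0.37 from the median of random lists matched on expression (−0.05, middle 95% of −0.24 to 0.12). With TMM scaling it was at −0.32 (−0.48 to −0.01). Sex (−0.43) may account for it and cannot be told apart from other differences between the 2 libraries. The intervals given here span the genes of the list. Spread between cells, such as in how many of the 123 female and 100 male cells were dividing, was not tested.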

How the results depend on the processing

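Of 22 alternatives, 3 were chosen after the results were seen: total UMIs as the only scaling, the background of barcodes with 200 UMIs or more but under 500, and equal weights for somatic clusters. The cause of the changes given here was not tested, except where stated. With the UMI minimum doubled, PGC-like cells were 3.20% of the female library. DESeq2 called 3350 genes higher and 3507 lower, and 838 genes had no adjusted p. Over all alternatives the female share lay between 2.14 and 3.20% and the male share between 1.26 and 1.57%. The Z-linked median in PGC-like cells was 0.95 with 70 cells per library thinned to 16038 UMIs each, a setting that left fewer genes, and lay between 0.76 and 0.95 over all alternatives. In somatic cells it lay between 0.60 and 0.63.

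The sums of PGC-like and somatic cells from 1 library were paired by design. With no replicate block, 3943 genes were higher and 4883 lower, and 8686 of the 9605 calls were kept. With no filter on low counts 3975 and 5590 of 20275 genes were called. Total UMIs as the only scaling gave 5324 and 3905. The other alternatives tested in edgeR gave between 4157 and 4440 higher and between 5093 and 5361 lower. Clustering resolutions of 0.5 and 2.0 gave the same PGC-like class and so tested nothing further. Leaving out a library left no residual degrees of freedom, so those values had no test. UHRF1 then lay between −0.010 and 0.75, and was below 0 without the female library.

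For 134 named results of PGC-like over somatic level, 2338 of 2480 alternative values kept direction and call, 54 lost the call, 87 moved and 1 changed sign. The 2 clustering resolutions, which could change nothing, added 134 unchanged values each. All 87 moved values came from leaving out a library. Without the female library 45 moved and 57 stayed within 1 SE, and without the male library 42 moved and 66 stayed. Lost calls were mainly in DESeq2 (22), without the block (7), without the filter (6) and with total UMIs (6). INS lost its call in 9 alternatives, and GINS2 and UHRF1 in 6 each. Ratios in a single library resting on fewer than 3 UMIs on a side (57) were left out of these counts, and 4 of them lay on the other side of 0, for INS (0.07), INHBA (0.01), SHH (1.15) and GINS2 (0.30) in the male library. This limit was set after those values were seen.

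For male over female level, 706 of 723 alternative values in PGC-like cells and 691 of 745 in somatic cells stayed within counting error. The 2 clustering resolutions, which could change nothing, added 60 such values each in PGC-like and 57 each in somatic cells. With somatic clusters weighted equally, PDZK1 (−1.11) and CYP17A1 (−0.13) changed sign. The PDZK1 value does not hold the mesonephric-like cells that carried 90.6% of its male UMIs. Over all alternatives, list medians in PGC-like cells lay between −0.44 and −0.28 for mitosis, −0.39 and −0.28 for piRNA, −1.06 and −0.87 for meiosis (without thinned cells, where no member kept 100 UMIs), and 0.12 and 0.39 for pluripotency genes. In somatic cells they lay between −0.23 and −0.14 for retinoic acid, 0.11 and 0.37 for steroid synthesis, 0.23 and 0.77 for male sex determination, 0.10 and 0.21 for replication, and 0.01 and 0.18 for mitosis genes. Depth limited FOXL2 (16 and 11 UMIs) and CYP19A1 (1 and 8) most among the sex determination genes, and SMC1B, STAG3 and HORMAD1 were the only meiosis genes with 100 UMIs in PGC-like cells.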

Other observations

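Erythroid-like, endothelial-like and supporting-like cells were compared between the libraries as well. In erythroid-like cells all 9 DNA replication genes with enough UMIs were higher in the male library, with a median log2 ratio of 0.35 (percentile 99.6 of random lists), and all 19 Z-linked genes were higher (median 0.72). In endothelial-like cells early response and heat shock genes were lower in the male library, with a median of −0.33 (percentile 0.00), and FOS was at 421 CPM in the female and 170 CPM in the male library. The Z-linked median was 0.61 in endothelial-like and 0.65 in supporting-like cells. Early response and heat shock genes were lower in all 10 cases in male supporting-like cells (median −0.60), whereas 11 of 12 mitosis genes were higher (median 0.36, percentile 100). Classes did not agree, since 5 of 7 early response and heat shock genes were higher in male erythroid-like cells (median 0.18, percentile 94.9) and 3 of 13 mitosis genes in male endothelial-like cells (median −0.11, percentile 0.31). These are values of 1 library per sex, and the lists described here were picked after their values were seen.

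Pou5f3 was at 22.2 CPM in female and 19.6 CPM in male somatic cells, where free RNA from barcodes with 1 to 100 UMIs would bring 1.44 and 1.5 CPM. DAZL was at 5.12 and 2.14 CPM in the same cells, where it would bring 2.82 CPM in each library.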
